A study of Drosophila melanogaster with 6 samples.

How the data were processed

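RNA abundance was measured by RNA sequencing of total RNA from dissected larval fat bodies of Drosophila melanogaster, the organ that stores fat and glycogen and secretes most haemolymph proteins. The 6 libraries fall into 2 groups of 3 by the genotype label. In both groups the cg-Gal4 driver, active in the fat body, expressed a short hairpin RNA, which targeted either GFP (the control, shGFP) or circbabo(5,6,7,8S), a circular RNA of the babo gene (shcircbabo). The labels number the replicates 1 to 3 in each group but do not say that they came from separate crosses, cultures or sets of larvae, so the p-values measure the spread between these samples, which can be partly technical.

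Per the submitters' processing notes, the reads were trimmed with Trim Galore 0.4.4, aligned with STAR to the dm6 genome build and assigned to genes with featureCounts 2.0.1 of the Subread package. The STAR version, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited a table of whole-number counts per gene, not normalised, and a table of RPKM values. The deposited RPKM values equal the counts divided by gene length and by the column total: all 76981 values above 0, or 100.0%, were recomputed within a relative tolerance of 0.0001. The gene lengths this implies equal the exon unions of the Ensembl release 115 annotation for 99.4% of the genes, and that annotation supplied positions and symbols. The table holds 14805 genes, of which 14761 matched a symbol and 44 did not and were not named. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies (Lsp1, GstD, Mst84D, Cyp12d1) are uncertain because the counting can split or drop their shared reads.

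Total counts per library ran from 7494415 to 24669266, and 14 rRNA genes took 30.53% to 41.67% of them. The rRNA genes stayed in the library sizes of the main test. The counts of the replicate pairs within a group differed by a chi-square per degree of freedom of 13.0 to 80.0, so no library repeated another. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers.

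The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with filterByExpr (minimum count 10, minimum total 15), TMM normalisation, robust dispersion and quasi-likelihood fits, and group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Levels are CPM on the TMM scale, as mean ± SD over 3 libraries. A gene at 0 in all libraries of a group was given a bound from 3 counts over that group's summed effective library sizes. Fold changes are shcircbabo against shGFP.

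Before the data were examined, 37 gene lists with 974 members were fixed. They cover fat body pathways, markers of other tissues that a dissection can carry along, and markers of sex and of transgenic strains. Each list with at least 3 tested genes, 36 in all, was tested with camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. No list that camera called held its call when the correlation was estimated from the data. The named genes also followed a fixed rule: babo, then the 10 genes with the largest log2 fold change in each direction among those called, with a mean of at least 5 CPM and all libraries of one group above all of the other, then up to 4 called members of each list by absolute log2 fold change, or up to 2 of the most abundant members where none was called. The rule gave 112 different genes, some of them under several lists. A gene that the rule names is not reported here.

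The alternatives fixed in advance were RLE normalisation, library sizes alone, no expression filter, a filter on CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, limma on log2(RPKM + 1) and log2(RPKM + 0.1), stricter thresholds, other list tests, and leaving out each library in turn. Added after seeing the data were the total without rRNA genes as the library size, the mean of the male germline markers as a covariate, and the calls without chromosome 2 genes.

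The procedure was tested on simulated data drawn from these libraries' means and sizes, in which 9503 genes passed the filter for edgeR. Genes were drawn independently, which leaves out variation shared between genes, and 43 to 50 tested genes were changed at each fold. The shares below hold for that setting only. It recovered 96% of the genes made 4-fold higher and 97.8% of those made 4-fold lower, but 58% and 41.9% of those changed 2-fold, and 7.28% of its calls were false. A 2-fold change can therefore be missed at this depth and number of libraries.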

Results

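The comparison asked which RNAs of the larval fat body differ when circbabo(5,6,7,8S), a circular RNA of the babo gene, is targeted by a hairpin RNA, against a hairpin that targets GFP. Fat bodies came from wandering larvae of the last instar, with 3 libraries per genotype. The shGFP libraries held 24669266, 8852444 and 19879629 counts, and the shcircbabo libraries 7494415, 8642326 and 9585188, so the control group was sequenced more deeply. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.95 to 0.972 between libraries of one group and 0.885 to 0.964 between groups. The first principal component held 57.4% of the variance and placed the 3 shGFP libraries at -25, -53 and -14 and the 3 shcircbabo libraries at 14.4, 48 and 29.6.

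The babo gene (FBgn0011300, 2R from 8952339 to 8962796 on dm6), from whose exons the targeted circular RNA is made, encodes a type I Activin receptor. It had 24.4, 14.9 and 30.0 CPM in shGFP and 30.6, 41 and 36.8 CPM in shcircbabo. Its mean was 23.1 ± 7.63 CPM (SD, n = 3) against 36.1 ± 5.23 CPM, with a log2 fold change of 0.63 ± 0.24 (SE). It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0785). Counts per gene add linear and circular reads, so they do not measure the circular RNA, and the knockdown itself was not checked here. The gene passed the test without shGFP replicate 3 (log2 fold change 0.86) and without the expression filter (0.64). Its log2 fold change was 0.29 under the total without rRNA and -0.15 with the male germline covariate, without a call.

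Of 9676 genes tested, 491 were called higher and 933 lower in shcircbabo by edgeR's quasi-likelihood test, so 34.5% of the called genes were higher. This split depended on the scaling. With library sizes alone 127 were higher and 1619 lower (7.27% higher), and with the total without rRNA 142 and 2124 (6.27%), while DESeq2 gave 758 and 858 (46.9%). Against TMM, these first 2 scalings moved the median log2 fold change of all genes by -0.28 and -0.34, and fold changes below are on the TMM scale. The counts also rested on single libraries. They were 71 higher and 82 lower without shcircbabo replicate 2, 109 and 179 without shcircbabo replicate 3. They were 197 and 288 without shGFP replicate 2, and 810 and 1149 without shGFP replicate 3. The lower genes numbered 539 without shGFP replicate 1.

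**Figure D1:**
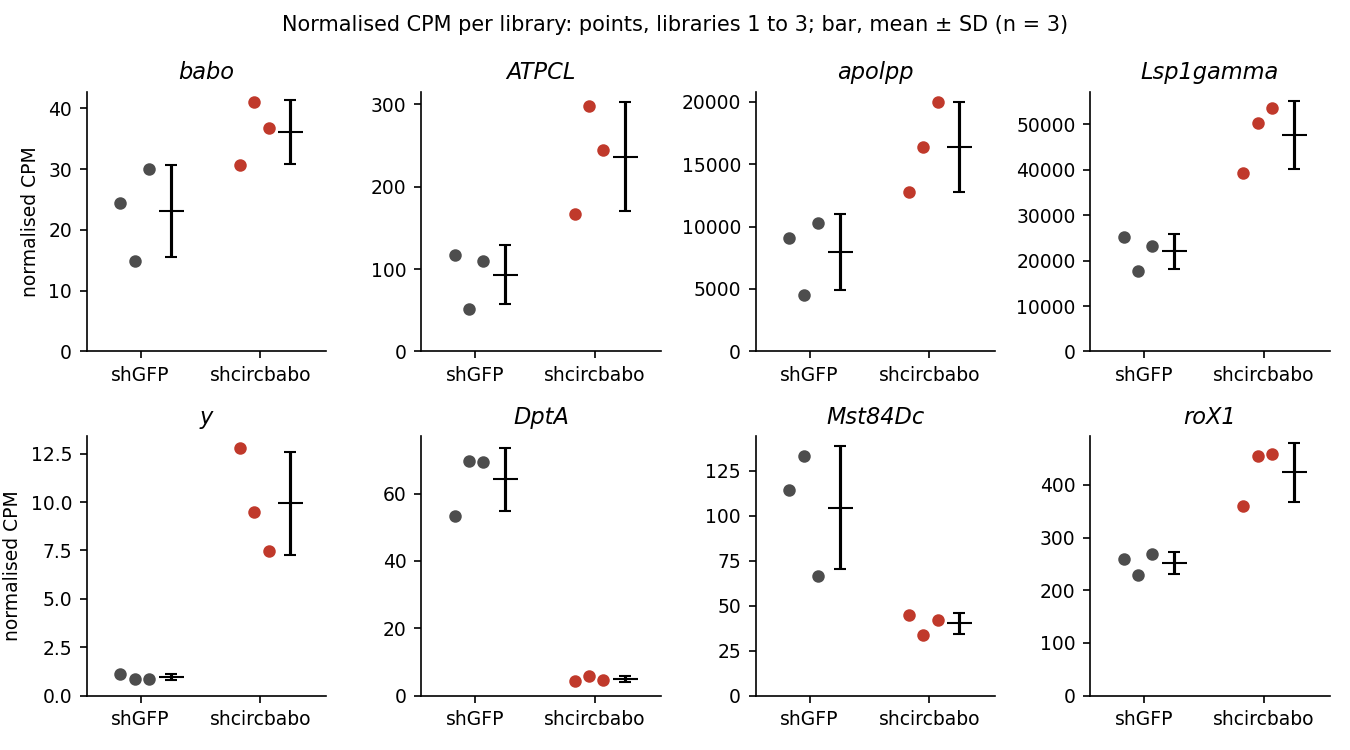
Normalised CPM (y axis, starting at 0) of 8 genes in each library, grouped by genotype (x axis), with points for libraries and bars for the mean ± SD of 3 libraries. DptA lies near 64.2 CPM in shGFP and 4.95 CPM in shcircbabo, y moves the other way, and the babo groups do not overlap but the gene was not called.

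Among called genes with a mean of at least 5 CPM whose groups did not overlap, those that rose most included y, a pigmentation gene, from 0.946 ± 0.158 to 9.92 ± 2.66 CPM (log2 fold change 3.35 ± 0.32), and Sodh1, a sorbitol dehydrogenase, from 22.5 ± 12.8 to 174 ± 22.7 CPM (2.93 ± 0.38). CadN, a neuronal cadherin, rose from 6.02 ± 2.42 to 33.3 ± 7.85 CPM (2.43 ± 0.28), and Uro, the urate oxidase, from 5.23 ± 3.56 to 28.4 ± 1.53 CPM (2.36 ± 0.47). The other genes of the 10 that rose most under this rule were CG8642 (log2 fold change 3.03), CG34215 (2.76), l(2)37Cb (2.56), CG9119 (2.13), the glutathione transferase gene GstD10 (2.12) and the potassium channel gene Shawl (1.97). Among genes that fell, under the same rule, CG14273 (2L, start 8342695) went from 11.5 ± 1.09 CPM to 0 counts in all 3 shcircbabo libraries, at least 88.5-fold lower. DptA, which encodes the antimicrobial peptide Diptericin A, went from 64.2 ± 9.36 to 4.95 ± 0.897 CPM (log2 fold change -3.70 ± 0.24, adjusted p = 3.61e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CG7299 (-4.20), Pgant4 (-2.69), CG31639 (-2.13), Trxr2 (-1.91), CG14505 (-1.85), Dic3 (-1.82), Tep1 (-1.82) and spag4 (-1.75) complete the 10 that fell most under it, and some less abundant genes changed more. Pgant4, Trxr2 and Dic3 were highest in shGFP replicate 2 and lowest in shcircbabo replicate 2, as was the male germline marker mean.

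**Figure D2:**
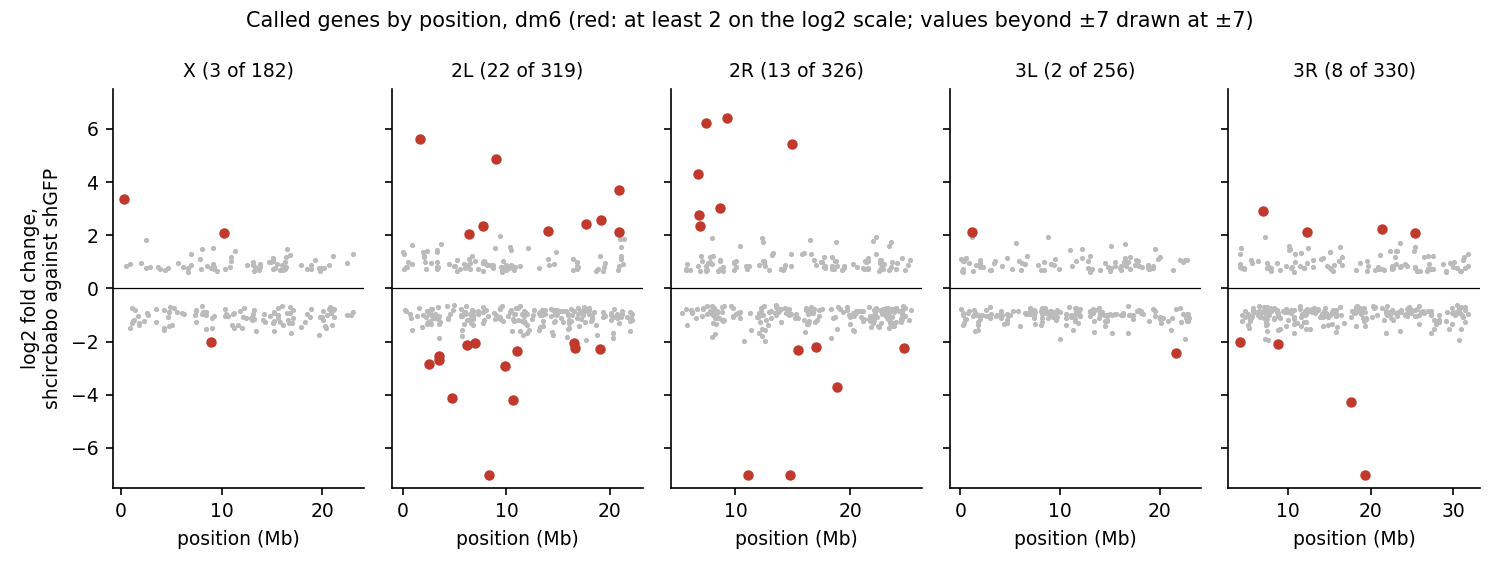
Log2 fold change (y axis) against position in Mb on the dm6 arms (x axis) for every called gene on 5 arms, with genes at an absolute log2 fold change of at least 2 in red. The red genes number 22 on 2L and 13 on 2R, against 3 on X, 2 on 3L and 8 on 3R.

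Some genes of lipid synthesis and fatty acid oxidation rose, and 0 fell. Of 23 tested genes of fatty acid and triglyceride synthesis 7 were higher and 0 lower (10 higher adjusted over the list alone). The median log2 fold change was 0.67 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000551; adjusted p = 0.467 with an estimated correlation). They included ATPCL, the ATP citrate lyase that supplies acetyl-CoA (92.8 ± 35.5 to 237 ± 65.8 CPM, log2 fold change 1.35), the transcription factor gene SREBP (1.10), the acyl-CoA synthetase gene bgm (1.09) and Gpdh1 (0.91), whose sign turned with the male germline covariate. Of 23 beta-oxidation genes 8 were higher and 0 lower (13 adjusted over the list alone; median 0.55, camera adjusted p = 1.23e-06 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). They included the neighbouring peroxisomal oxidase genes Acox57D-p (1.02) and Acox57D-d, and Had1 (0.99).

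A few lipid storage and transport genes rose, and 0 fell. Of 11 lipid droplet and lipolysis genes 2 were higher and 0 lower (5 adjusted over the list alone; median 0.50, camera adjusted p = 0.00332 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). These were the adjacent genes dob, a lipase gene (1.03), and Lsd-2, a perilipin (0.74). Of 16 lipoprotein and lipid transport genes 4 were higher and 0 lower (6 adjusted over the list alone; median 0.45, camera adjusted p = 0.00372 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). These were fabp (1.34), apolpp, the precursor of the main haemolymph lipoprotein (7980 ± 3056 to 16410 ± 3634 CPM, 1.04), Apoltp (1.02) and Mtp (0.84). None of 21 phospholipid and sphingolipid genes was called (0 adjusted over the list alone), although the list as a whole was higher (median 0.20, camera adjusted p = 0.0115 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). Under the total without rRNA its median was -0.13. Its most abundant members had log2 fold changes of 0.18 (Pect) and 0.61 (oys).

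Some genes of carbohydrate and methionine metabolism rose as well. Of 27 genes of glycolysis, trehalose and glycogen metabolism 3 were higher and 0 lower (10 adjusted over the list alone; median 0.43, camera adjusted p = 4.35e-05 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). AGBE, the glycogen branching enzyme (1.27), Treh, trehalase (0.76), and Hex-A, a hexokinase (0.66), rose. Of 15 genes of methionine, serine and C1 metabolism 5 were higher and 0 lower (9 adjusted over the list alone; median 0.62, camera adjusted p = 0.000193 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). They were led by CG3999 (161.6 ± 67.7 to 456 ± 112 CPM, 1.49), Sam-S, the S-adenosylmethionine synthetase (1.29), Sardh (0.83) and CG6415 (0.68). The sugar sensing list of 9 genes was not called (camera adjusted p = 0.121 with Benjamini-Hochberg adjustment), with tobi (2.09) and Mondo (0.91) higher and Gal (-0.88) lower, or 4 higher and 1 lower adjusted over the list alone. Together the 6 lists of lipid, carbohydrate and methionine metabolism that camera called, phospholipids left out, held 115 tested genes, of which 29 were called higher and 0 lower. With the total without rRNA 9 of these 29 were still called and with library sizes alone 7, and the 6 list medians stayed above 0 under both. With the male germline covariate, which separates the groups completely, 0 genes of these 6 lists were called. The list medians then ran from -0.113 (glycolysis, trehalose and glycogen) to 0.198 (beta-oxidation). In shGFP replicate 2, which lay at -53 on the first principal component, ATPCL had 52.1 CPM against 117 and 110 CPM in the other shGFP libraries, and apolpp 4520 against 9100 and 10300 CPM. Of the 29 calls 14 held without that library, 2 without shcircbabo replicate 2 and 9 without shcircbabo replicate 3. The other omissions kept 21 (shGFP replicate 1), 22 (shGFP replicate 3) and 27 (shcircbabo replicate 1). The median log2 fold change of the 29 was 0.96 (interquartile range 0.719 to 1.043) with all libraries. It was 0.765 (0.646 to 0.942) without shGFP replicate 2, 0.78 (0.608 to 0.963) without shcircbabo replicate 2 and 0.889 (0.712 to 1.115) without shcircbabo replicate 3. It was 1.045 (0.818 to 1.222) without shGFP replicate 1, 0.943 (0.811 to 1.127) without shGFP replicate 3 and 1.079 (0.839 to 1.208) without shcircbabo replicate 1. All 29 stayed above 0 in every omission, and calls were lost where the median was higher as well as where it was lower. The 29 were chosen as called higher with all libraries, and each omission reuses most of these. Their signs and medians were therefore largely fixed in advance.

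All 3 Lsp1 hexamerin genes and 3 secretory pathway genes rose. Of 11 storage protein and related haemolymph protein genes 3 were higher and 0 lower, also adjusted over the list alone, and the list was not called (median 0.31, or -0.03 under the total without rRNA, camera adjusted p = 0.0502 with Benjamini-Hochberg adjustment). The 3 were Lsp1gamma (22060 ± 3874 to 47790 ± 7479 CPM, 1.11), Lsp1beta (0.92) and Lsp1alpha (0.87), hexamerin subunits whose related sequences can share reads. Storage proteins took 29.25% to 33.05% of the counts without rRNA in shGFP and 36.93% to 40.11% in shcircbabo. Of 24 genes of the unfolded protein response and secretory pathway 3 were higher and 0 lower (5 adjusted over the list alone; median 0.45, camera adjusted p = 2.32e-05 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). Sec61alpha (0.96), Sec31 (0.80) and Sec61gamma (0.78) rose. Under the total without rRNA the list median was 0.09 and only Sec61alpha (0.61) of these 3 was called, and with library sizes alone the median was 0.15 and none of them was called. Of 21 secreted fat body signals 3 were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 0.00188 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). The median of this list was 0.07 under the total without rRNA. The neighbouring genes Idgf1 (1.09) and Idgf2 (0.71) and the TNF ligand gene egr (1.02) rose, and Obp44a (-0.97), which was highest and lowest in the same libraries as the male germline marker mean and turned sign with that covariate, fell.

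Of 24 ecdysone response genes 3 were higher and 0 lower, also adjusted over the list alone (median 0.37, camera adjusted p = 0.00235 with Benjamini-Hochberg adjustment, adjusted p = 0.467 with an estimated correlation). Uro, MsrA (0.98) and Oatp74D, an ecdysone importer (0.87), rose. Uro is also in the list of oenocyte, trachea and Malpighian tubule markers, so its rise may come from another tissue. Under the total without rRNA the list median was 0.04. The signs of MsrA and Oatp74D turned with the male germline covariate. Of 29 autophagy and lysosome genes 2 were higher and 1 lower (1 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 0.00568 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). The median was -0.04 under the total without rRNA. Atg17 (0.95) and Atg1 (0.77), both of the initiating kinase complex, rose, the latter turning sign with the germline covariate, and Atg8b (-0.86), which was highest and lowest in the same libraries as the male germline marker mean, fell.

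Of the antimicrobial peptide genes 4 fell and 8 were not called, and no tested Toll or Imd pathway component was called lower. Of 12 tested peptide genes 4 were lower and 0 higher (5 lower adjusted over the list alone; median -1.16, camera adjusted p = 0.000551 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). Besides DptA these were Dro (6.89 ± 3.35 CPM to 0 counts, at least 53.2-fold lower), Mtk (4.37 ± 0.827 to 0.866 ± 0.0955 CPM, -2.31) and DptB (-1.52). All 4 lie on 2R, and 10 of the 12 tested genes lie on chromosome 2. The remaining members, Drs (-0.61 ± 0.36) and Drsl5 (0.20 ± 0.39), lie on 3L and were not called. Of 30 Toll and Imd pathway genes 4 were higher and 0 lower, also adjusted over the list alone (median 0.34, camera adjusted p = 0.00105 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation), with a median of -0.01 under the total without rRNA. The ligand spz (0.91), its protease SPE (0.85), the NF-kappaB gene Rel (0.69) and the receptor Tl (0.64) rose, but all 4 lost their calls under the total without rRNA (0.56, 0.49, 0.35 and 0.29), with library sizes alone and with the replicate block. The 9 JAK-STAT and turandot genes were not called as a list (camera adjusted p = 0.204 with Benjamini-Hochberg adjustment). Of its thioester proteins Tep4 (0.95) and Tep2 (0.67) rose and Tep1 fell, or 3 higher and 1 lower adjusted over the list alone.

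Of 42 detoxification and oxidative stress genes 12 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.38, camera adjusted p = 0.000551 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). The list median was 0.03 under the total without rRNA. Cyp12d1-d went from 6.43 ± 2.04 CPM to 0 counts, at least 49.6-fold lower, but shares nearly all its sequence with Cyp12d1-p. The cytochrome P450 gene Cyp6a2 rose from 0.151 ± 0.151 to 3.78 ± 1.11 CPM (4.32), and Cyp6a8, with 3 counts in shGFP, had a ratio of 49.5 (95% counting interval 16.9 to 240). Of the 16 heat shock and chaperone genes Hsp60C (328 ± 47.1 to 159 ± 33.5 CPM, -1.05) and Hsc70-1 (-0.91) fell and 0 rose (3 lower adjusted over the list alone). Both were highest and lowest in the same libraries as the male germline marker mean, and Hsc70-1 turned sign with that covariate. The list was not called (camera adjusted p = 0.282 with Benjamini-Hochberg adjustment).

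Signalling lists moved little gene by gene. None of 13 TGF-beta and Activin genes was called, also adjusted over the list alone, and the list as a whole was higher (median 0.34, camera adjusted p = 0.0115 with Benjamini-Hochberg adjustment, adjusted p = 0.467 with an estimated correlation), with a median of 0.00 under the total without rRNA. The Activin-like ligand daw had 116 ± 15.1 and 137 ± 11.0 CPM (log2 fold change 0.25) and the Smad gene Smox 61.8 ± 12.1 and 75.6 ± 13.3 CPM (0.29, or -0.06 under the total without rRNA and -0.47 with the male germline covariate). Of 26 insulin, TOR and FoxO genes 0 were higher and 1 lower, also adjusted over the list alone (median 0.32, camera adjusted p = 0.00568 with Benjamini-Hochberg adjustment, adjusted p = 0.477 with an estimated correlation), and the median was -0.03 under the total without rRNA. The gene that fell was Thor, the translation inhibitor 4E-BP (273 ± 71.7 to 107 ± 19.9 CPM, -1.35), which starts at 3478434 on 2L, next to Pgant4 at 3472603. Of 13 small RNA pathway genes Dcr-2 (0.99), drosha (0.90) and AGO1 (0.75) rose and loqs (-0.99), which was highest and lowest in the same libraries as the male germline marker mean, fell, or 5 and 1 adjusted over the list alone. The small RNA list was not called (camera adjusted p = 0.401 with Benjamini-Hochberg adjustment).

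Housekeeping lists were not called. No gene of 81 cytosolic ribosomal proteins (median -0.04, camera adjusted p = 0.947 with Benjamini-Hochberg adjustment) or of 31 proteasome subunits (median -0.07, camera adjusted p = 0.947) was called, also adjusted over each list alone. Under the total without rRNA these medians were -0.40 and -0.41. RpL5 (-0.01), RpS25 (0.09), Rpn2 (0.26) and Rpn6 (-0.05) were the most abundant by the rule. Of 66 oxidative phosphorylation genes ND-B17 (-0.84) and ND-B12 (-0.71) fell (0 adjusted over the list alone; camera adjusted p = 0.289 with Benjamini-Hochberg adjustment). Of 24 DNA replication genes E2f1 (0.70) rose and CycB (-0.77), which was highest and lowest in the same libraries as the male germline marker mean and turned sign with the germline covariate, fell (0 adjusted over the list alone; camera adjusted p = 0.501 with Benjamini-Hochberg adjustment).

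**Figure D3:**
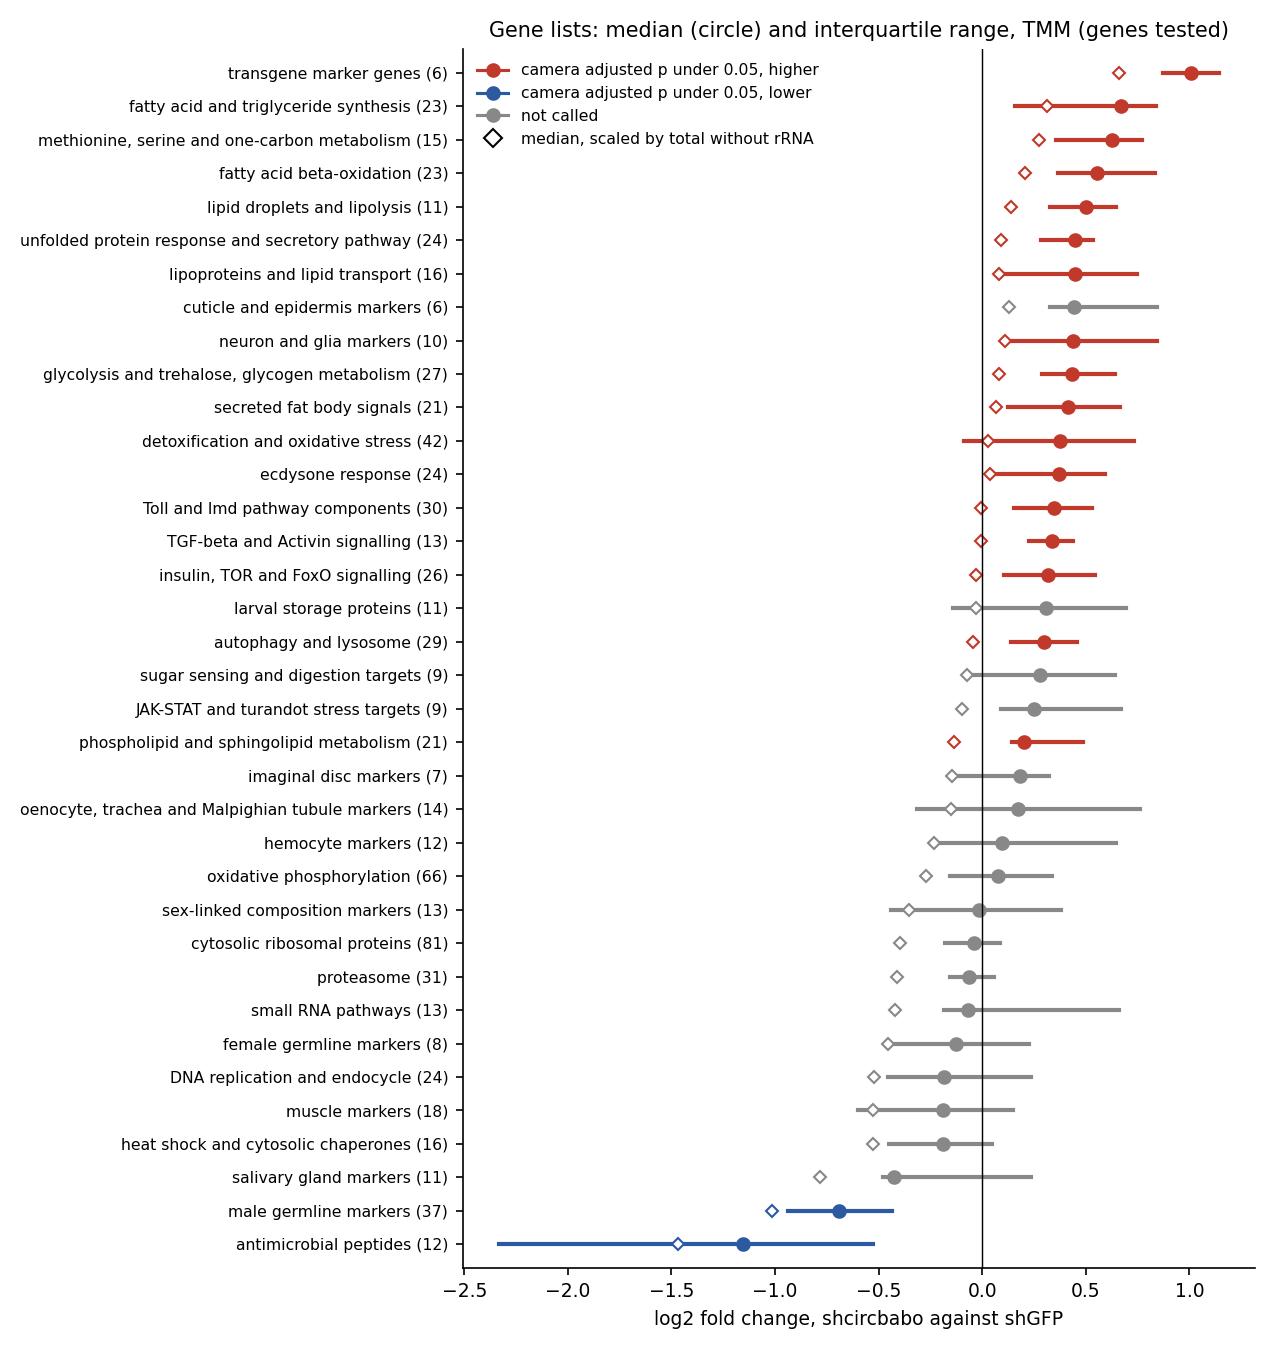
Median log2 fold change (circles) and interquartile range (lines) of the tested members of 36 gene lists under TMM, with diamonds for the median under the total without rRNA, which lies lower in every list. Male germline markers and antimicrobial peptides lie lowest, at medians of -0.69 and -1.16.

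Markers of the male germline were lower in shcircbabo. All 37 tested genes had a negative log2 fold change and 17 were called lower (24 adjusted over the list alone; median -0.69, camera adjusted p = 2.09e-08 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). The spermatid genes Mst84Dc (104.5 ± 34.2 to 40.1 ± 5.94 CPM, -1.38), Mst84Da (-1.37), Mst84Db (-1.28) and Mst84Dd (-1.19), neighbours with related sequences, fell. The mean log2 CPM of the markers was 5.39, 5.42 and 5.13 in shGFP and 4.82, 4.29 and 4.69 in shcircbabo. With this mean as a covariate, which separates the groups completely, 6 genes were higher and 6 lower. This fit cannot tell testis RNA from genotype. Of the 13 sex-linked markers, some of which are also male germline markers, the Y-linked dynein gene kl-3 fell from 16.7 ± 1.83 to 8.37 ± 2.35 CPM and the male-specific noncoding RNA roX1 (lncRNA:roX1) rose, from 252 ± 20.5 to 424 ± 55.9 CPM (0.75), or 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.955 with Benjamini-Hochberg adjustment).

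**Figure D4:**
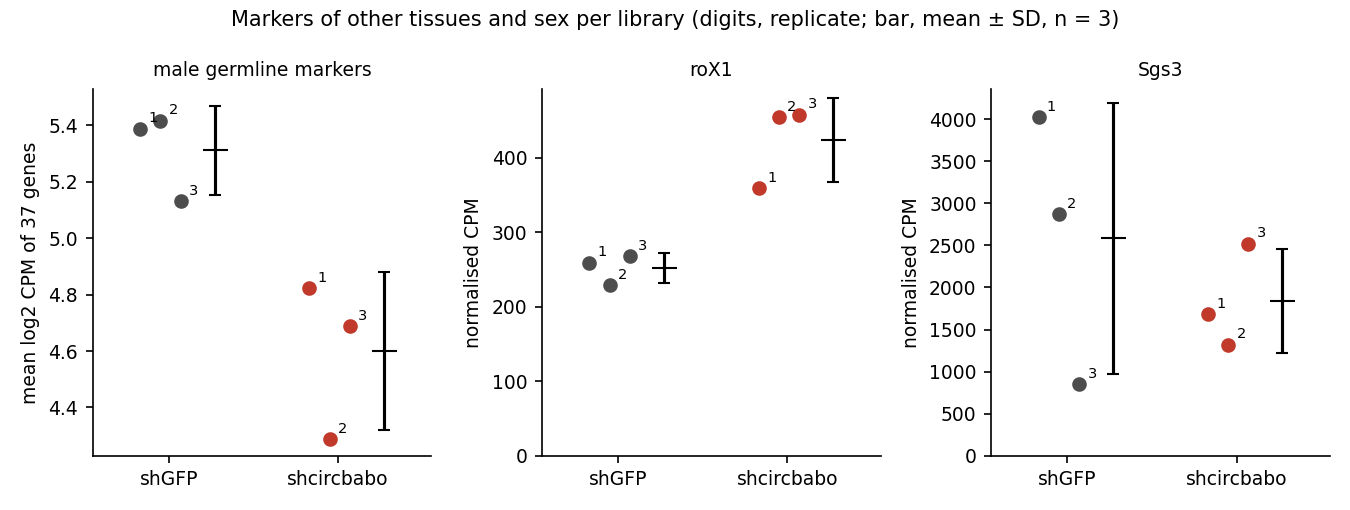
Mean log2 CPM of 37 male germline markers and normalised CPM of roX1 and Sgs3 (y axes) in each library by genotype (x axes), with digits for the replicate and bars for the mean ± SD of 3 libraries. The germline mean is 5.13 to 5.42 in shGFP and 4.29 to 4.82 in shcircbabo.

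Markers of other tissues moved in both directions. Salivary gland genes were not called, also adjusted over the list alone (11 tested, camera adjusted p = 0.588 with Benjamini-Hochberg adjustment, where the median of -0.43 and camera's upward direction differ in sign), with Sgs3 at 2583 ± 1609 and 1843 ± 616.5 CPM and Sgs4 at a log2 fold change of -0.47. Of 10 neuron and glia markers cpx (1.53) and moody (0.95) rose, also adjusted over the list alone, and the list was higher (median 0.44, camera adjusted p = 0.0182 with Benjamini-Hochberg adjustment, adjusted p = 0.467 with an estimated correlation). Of 12 hemocyte markers NimC1 (2.17) rose and Fer3HCH (-0.96), which was highest and lowest in the same libraries as the male germline marker mean and turned sign with the germline covariate, fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.29 with Benjamini-Hochberg adjustment). Of 18 muscle markers Zasp52 (1.29) rose and Act87E (-0.85) fell, also adjusted over the list alone (camera adjusted p = 0.68 with Benjamini-Hochberg adjustment). Of 8 female germline markers CycB3 (-0.80), which was highest and lowest in the same libraries as the male germline marker mean, fell, also adjusted over the list alone (camera adjusted p = 0.68 with Benjamini-Hochberg adjustment). Of 14 oenocyte, trachea and Malpighian tubule markers Uro and Irk1 (1.40) rose, or 3 adjusted over the list alone (camera adjusted p = 0.34 with Benjamini-Hochberg adjustment). Of 6 cuticle markers only y was called, also adjusted over the list alone (camera adjusted p = 0.105 with Benjamini-Hochberg adjustment). No gene of 7 imaginal disc markers was called, also adjusted over the list alone (camera adjusted p = 0.512 with Benjamini-Hochberg adjustment), with ap at 0.40 and sd at 0.18. A single midgut marker was tested, LManII (0.89), which rose.

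The strain marker list, which holds eye and body colour genes and the collagen genes from which the driver derives, was higher (median 1.01, camera adjusted p = 0.00101 with Benjamini-Hochberg adjustment, adjusted p = 0.458 with an estimated correlation). Of its 6 genes y, v (27.4 ± 3.00 to 61.7 ± 13.7 CPM, 1.17) and ry (54.4 ± 17.4 to 114 ± 12.3 CPM, 1.07) rose and 0 fell, also adjusted over the list alone.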

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

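The total without rRNA, the male germline covariate and the omission of chromosome 2 were chosen after seeing the data. The higher and lower calls (491 and 933) were 127 and 1619 with library sizes alone, 142 and 2124 with the total without rRNA, 123 and 1834 on log2(RPKM + 1), 98 and 1603 on log2(RPKM + 0.1) and 5 and 23 on log2(RPKM + 1) with no filter. They were 739 and 1179 with no filter on counts, 758 and 858 with DESeq2 and 418 and 614 with limma-voom, and the cause was not tested. Stricter thresholds left 100 and 171 at an adjusted p under 0.01 and 183 and 441 at an absolute log2 fold change of at least 1, and omitting chromosome 2 left 249 and 456 of 5858 genes tested. RLE normalisation (655 and 876) and the CPM filter (484 and 910) stayed within 1.5 times the main counts. Leaving out 1 library gave 71 to 810 higher and 82 to 1149 lower. The lists called higher (17) and lower (2) were 0 and 0 with an estimated correlation, 3 and 1 with fry (of which larval storage proteins were not among the 19), 2 and 2 with the germline covariate, 18 and 1 without chromosome 2, where the peptide list had too few genes to be tested, and 16 to 19 and 2 to 3 without 1 library. Under the total without rRNA they were 18 and 2, and with library sizes alone 19 and 2. Camera compares a list with the other tested genes, so these calls do not address a shift of all genes. The log2 fold change of babo passed the test with no filter (0.64) and ranged from 0.42 to 0.86 without 1 library.

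With the replicate number as a block 90 genes were higher and 132 lower, all also called without it, and no list call changed. Deviations of same-numbered libraries correlated across genes at -0.067, -0.113 and -0.033, and no library correlated best with its own number. With 3 libraries per group these values cannot tell whether the numbers mark pairs.

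With the male germline covariate 6 genes were higher and 6 lower, of which 3 and 4 were among the main calls. This term leaves fewer degrees of freedom and separates the groups completely. The higher calls it added were BomBc1 (log2 fold change 31.6), BomS5 (20.5) and BomS2 (16.4), against 0.40, -1.30 and -0.26 in the main fit. Such values are extrapolations, so sign turns and lost calls in this fit cannot be read as a correction for testis RNA. Signs turned for Gpdh1 (-0.16), Obp44a (0.14), MsrA (-0.36), Oatp74D (-0.13), Atg1 (-0.10), Hsc70-1 (0.14), CycB (0.36) and Fer3HCH (0.34). Of genes not called, babo (-0.15), Smox (-0.47), RpS25 (-0.18), Rpn2 (-0.02), Sgs3 (1.37) and Sgs4 (1.23) turned too. Of the 19 list calls only that of the strain marker genes held with this covariate. The other lists it called were salivary gland genes, higher, and ribosomal protein and oxidative phosphorylation genes, both lower. Directions turned, without a call, for the lists of TGF-beta, Toll and Imd, autophagy and detoxification genes (camera with Benjamini-Hochberg adjustment, adjusted p = 0.983 each), fatty acid synthesis (adjusted p = 0.827), and lipoproteins, glycolysis, ecdysone response and the secretory pathway (adjusted p = 0.666 each).

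Of the 99 called among the named genes, 66 lost their call without shcircbabo replicate 2, 52 without shcircbabo replicate 3, 38 without shGFP replicate 2, 29 without shGFP replicate 1, 35 with library sizes alone, 33 with the total without rRNA, 59 with the replicate block, 42 on log2(RPKM + 0.1), 39 on log2(RPKM + 1) and 92 on the latter with no filter, all with the same sign. Outside the 6 metabolic lists, those that lost it both with library sizes alone and with the total without rRNA were spz, SPE, Rel, Tl, Sec31, Sec61gamma, Idgf2, Mondo, Tep4, Tep2, MsrA, Oatp74D, Atg17, Atg1, E2f1, Dcr-2, drosha, AGO1, moody and roX1. With the germline covariate 86 lost it with the same sign and 8 turned sign. Camera was not run on DESeq2 values. Small changes can be missed: in libraries simulated without variation shared between genes, edgeR recovered 58% of genes made 2-fold higher and 41.9% of those made 2-fold lower.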

Other observations

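Gene families defined by a shared symbol prefix were tested after seeing the data, 115 families of at least 5 tested genes in 230 Fisher exact tests with Benjamini-Hochberg adjustment. Of 56 tested Cyp genes, which encode cytochrome P450 enzymes, 11 were called higher (odds ratio 4.65, adjusted p = 0.011, Fisher's exact test) and 4 lower (odds ratio 0.72, adjusted p = 1 by Benjamini-Hochberg), and 21 of the 56 were also in the fixed lists. Of 16 Mst genes, expressed in the testis, 9 were called lower (odds ratio 12.1, adjusted p = 0.000978, Fisher's exact test), with 7 of the 16 in the fixed lists. This test treats genes as independent, while genes of a family can vary together. The male germline list did not hold its camera call with an estimated correlation, so the p-values of families can be too small. The GstD genes (3 of 5 higher, adjusted p = 0.092), Nepl neprilysin-like genes (4 of 14 higher, adjusted p = 0.251) and Tim mitochondrial import genes (4 of 9 lower, adjusted p = 0.279) did not pass Fisher's exact test after adjustment. Of the genes called lower at an absolute log2 fold change of at least 2, lncRNA:CR43451, chosen after its values were seen, had 2.49 CPM in shGFP and 0 counts in shcircbabo.

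All tests below except the count of splits were chosen after the results were seen, and some replaced earlier versions. Those of testis RNA and read number for the large changes had argued against both causes, but the choice of genes had fixed their outcome. The test of depth had rested on 1 library, and the share of genes with the markers' extremes had been read without the opposite share. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one, which was the real split itself with 1424 genes. The highest of the others called 3, and 10 splits are too few for a share under 0.05.

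Male germline genes were lower in shcircbabo. The tables argue against fewer male larvae as the whole cause, because the male-specific roX1 (log2 fold change 0.749) and roX2 (0.379) did not fall. Their mean was 0.564 ± 0.147 (SE). Under the total without rRNA it was 0.216 ± 0.147, with roX1 at 0.398 and roX2 at 0.034, against a marker median of -1.02. Both RNAs are made in somatic cells, so a higher share of fat body RNA could raise them, and a smaller deficit of males stays open. Lower depth is argued against only as a loss of low counts. In libraries thinned to 7494415 counts each the marker mean was still lower in shcircbabo, by a log2 difference of -0.694 ± 0.19 (SE between libraries, medians of 20 draws). At full depth it was -0.712 ± 0.185. Thinning keeps the expected CPM of each gene, so for markers this abundant the result was largely fixed in advance and bears on no other effect of depth. A varying share of testis RNA, from tissue carried along in dissection, stays open: 66.2% of 916 genes called lower, markers left out, were highest in shGFP replicate 2 and lowest in shcircbabo replicate 2, as the marker mean was, against 14.2% of genes not called and 11.1% by chance. It cannot be told apart from other variation along the first principal component, whose extremes are these libraries, because 45.2% of genes called higher had the opposite extremes there. An effect of the genotype on the testis itself was not tested.

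Large changes concentrated on chromosome 2. Of 49 genes called at an absolute log2 fold change of at least 2, 35 (71.4%) lay there, against 44.4% of the 1374 other called genes (odds ratio 3.13, 95% interval 1.62 to 6.35, two-sided Fisher's exact test, p = 0.00021, or 0.00084 adjusted over 4 minimums). At a minimum of 1 the odds ratio was 1.18 (adjusted p = 0.12, Fisher's exact test over 4 minimums). The test treats genes as independent, but some are neighbours, such as Pgant4 and CG31776 on 2L, so its interval and p-values can be too small. Too few reads are argued against, since counting noise alone would bring 1.91 of all tested genes to 0.25 of their expected count or less, and 26 were called lower by at least 2. A varying testis share stays open for these 26, because in 4 of 9 left-out pairs of libraries the genes chosen without the pair had a median below the lowest germline marker, and in the others they did not. Different chromosome 2 backgrounds of the genotypes stay open too, and may include the antimicrobial peptide genes and CG14273, while y and v, on X, are genes often mutant in transgenic strains. The sources used here do not give the strains or insertion sites, and an effect of the hairpin was not separated from them.

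The 6 metabolic lists were higher, with a median log2 fold change of 0.54 over 115 members, 101 of them above 0. Under the total without rRNA the median was 0.198, with 80 above 0. Their spread of 0.208 (interquartile range divided by 2) is between genes and is not the error of the median. The median of all tested genes was -0.37 under this scaling and -0.03 under TMM, so the members lay above it under both. Storage proteins took a larger share of the total without rRNA in shcircbabo, so this total is not a neutral scale either. A TMM scaling pulled down by the genes that fell therefore cannot be told apart from a rise of these genes. The test of scaling was first run on the 29 called members alone. There the median of 0.603 exceeded the spread of 0.171 between genes and was read as arguing against scaling as the whole cause. It was changed to all members after that value was seen, because called members are picked for being high. A higher share of fat body RNA as testis RNA falls cannot be told apart either, because the members' median minus that of 6 storage protein genes was -0.15 for all members and, in the version run first, 0.266 for the called ones.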
